A study of Mus musculus with 8 samples.

How the data were processed

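The 8 libraries came from N134 cells, 4 labelled GFP-miR-431 and 4 labelled GFP-miR-LacZ. Per the labels' protocols, total RNA was isolated with a column kit, libraries were made with the Illumina TruSeq RNA kit, and paired reads of 51 bases were read on an Illumina HiSeq instrument. The submitters' processing notes name CASAVA 1.8.2, cutadapt, TopHat2 2.0.11 and Cufflinks 2.1.1 and the genome build mm9, with no role or order. The authors deposited 1 table of FPKM values, which are fragment counts scaled to transcript length and library size, for 23309 genes, of which 4406 were at 0 in all 8 libraries. The 75th percentile of FPKM lay between 14.5 and 14.7 in every library, a near equality that a scaling step would give, but no such step is named in the sources used here. FPKM does not keep the read counts, so no test on counts was run and no interval for counting error is given. Coordinates are those of the deposited table in mm9. A locus can span overlapping genes, and the strand of reads is not stated to have been used.

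Genes at 1 FPKM or more in at least 4 of the 8 libraries (11807 genes) were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1). The 2 groups were compared with no covariate, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 with no minimum fold. This design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. On simulated data with changes planted in 200 of 11807 genes, the test recovered 42% of changes of 0.5 and 89% of changes of 1 on the log2 scale, with 7 false calls. Each gene was drawn independently there and few genes were changed, so these rates need not carry over to the real calls.

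Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Adjusted values are over the 25 testable lists. The lists hold RasGAP genes, ERK pathway output, NF-kB targets, beta cell identity, neuroendocrine granules, other islet hormone cells, acinar, duct, fibroblast, endothelial and leukocyte markers, epithelial and mesenchymal genes, invasion, basement membrane, proliferation, interferon, stress responses, hypoxia, cholesterol synthesis, p53 targets, the microRNA pathway, the Dlk1-Dio3 locus, neuronal genes and mitochondrially encoded genes. The text names Dab2ip, then the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose higher group has a mean of at least 1 FPKM. Predicted genes and small RNA genes were left out of that part. It also names up to 3 called genes per list with at least 3 calls and 1 in other lists, and the 6 largest falls among called genes with an 8mer match. Some genes that the rule selects are not reported here. Rasa2, Ins2, Scg2, Insm1, Rbp4, Trf, the Serpina1 genes, and genes below the level tested were named after their values were seen.

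Seed matches were searched in 3′ UTRs of GENCODE M21, which is on another build than mm9 and was used for sequence, length and GC only. Of the 23309 genes, 23083 were matched to it by accession or symbol. The microRNA sequences were written from knowledge of the microRNA, not read from a file. The presence of a 7mer-m8 or 8mer match was a term in a linear model of fold change, and its coefficient was ranked among those of all arrangements of the same bases. On simulated data, a planted mean fall of 0.05 gave an interval below 0 in 98% of 50 draws. The draws shuffled fold changes over genes, so they hold no correlation between genes, and the 98% may overstate the precision.

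Libraries were compared for duplicates, and no 2 libraries of a group held near-identical values. Among genes below 0.1 FPKM, the ratio of 2 libraries was the same for 18.9% to 25.4% of genes in pairs among 6 libraries (within 0.02 on the log2 scale), for 1.87% to 2.58% in pairs of miR-LacZ 1 or miR-431 5 with those 6, and for 8.97% in the pair of these 2. These 2 libraries, 1 of each group, were therefore treated as a batch in added alternatives. Running medians over 31 genes along each chromosome were taken after the data were seen. Other alternatives changed the pseudocount (0.1 and 0.01), the level filter (none, or 5 FPKM), the scaling, the trend and the library weights, and left out each library in turn. Figures and tests on sequences and positions used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.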

Results

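RNA from N134 cells, a mouse cell line from a pancreatic beta cell tumor that the labels call a pancreatic neuroendocrine tumor line, was profiled by RNA sequencing in 8 libraries. In 4 libraries, numbered 5 to 8, the cells overexpressed microRNA-431 with a GFP marker (miR-431). In the other 4, numbered 1 to 4, they overexpressed a LacZ control construct in the same format (miR-LacZ). The title of the series names DAB2IP, a RasGAP that lowers Ras activity, as a target of the microRNA. The single comparison of the design asks which transcripts differ between miR-431 and miR-LacZ cells. The deposited table holds FPKM for 23309 genes, with sums of 521889 to 625005 FPKM per library, and 11603 to 11790 genes per library at 1 FPKM or more. Read counts per library are not given in the sources used here, so the depth behind each value is not known directly. If the commonest step of low values is 1 fragment, 1 fragment in 3 kb equals 0.00842 to 0.0104 FPKM in the 6 libraries other than 1 and 5. The labels do not say whether the 4 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels, and group values are means ± SD with n = 4.

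The transgene was read in every miR-431 library. Mir431 (chromosome 12, 110828378 to 110833613, mm9, a locus it shares with Rtl1 in the deposited table) was listed at 0 in all 4 miR-LacZ libraries, and at 18114, 32890, 37769 and 27269 FPKM in miR-431 libraries 5, 6, 7 and 8. These values made up 3.47% to 6.04% of the summed FPKM of the miR-431 libraries. The FPKM of so short a gene is not a dependable measure of its amount, and mature microRNA was not measured. Dab2ip (chromosome 2, 35405053 to 35586514, mm9) stood at 54.5 ± 7.74 FPKM in miR-431 and 73.3 ± 7.76 FPKM in miR-LacZ cells, which is 74.4% of the control level. Its log2 fold change was −0.42 (SE 0.119, limma adjusted p = 0.0236). The 2 groups overlapped, and an exact two-sided permutation test of the 4 against 4 levels gave p = 0.0571, where the smallest p this design allows is 0.0286. The call ended when miR-LacZ 1, miR-LacZ 2, miR-431 5 or miR-431 8 was left out, with log2 fold changes of −0.39, −0.39, −0.36 and −0.38 and limma adjusted p-values of 0.0530, 0.0683, 0.0592 and 0.0686. Without both libraries 1 and 5, whose low values follow another pattern than those of the other 6, it was −0.33 (limma adjusted p = 0.108), and within the pair of 5 and 1, which allows no test, the difference was −0.72. With all 8 libraries and a term for that pattern the call held (−0.42, limma adjusted p = 0.0250), and with the median of neighbouring genes removed it ended (−0.34, limma adjusted p = 0.0693). Of the 8 RasGAP genes tested, Dab2ip fell and Rasa2 rose by 0.29 (limma adjusted p = 0.0430), and 6 did not pass the threshold. Adjusted over the list alone, 2 rose and 3 fell. Rasa2, named after its value was seen, lost its call in 7 of the 8 fits that left out 1 library (all but that without miR-LacZ 1, adjusted p from 0.0630 to 0.122), and stood at 0.06 with the median of neighbouring genes removed.

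Peg10, an imprinted gene of retrotransposon origin, had the largest rise, from 0.117 ± 0.0476 to 34.4 ± 18.7 FPKM (log2 fold change 4.76). Its imprinted neighbour on chromosome 6, Sgce, rose from 0.0219 ± 0.00893 to 5.92 ± 1.27 FPKM (2.74). Gpr142, a receptor for aromatic amino acids, rose from 0.174 ± 0.0926 to 22.4 ± 3.55 FPKM (4.31), and the translation factor Eef1a2 from 1.74 ± 0.588 to 52.9 ± 9.83 FPKM (4.31). Ucn3, a beta cell peptide hormone, rose from 1.73 ± 1.24 to 37.3 ± 7.95 FPKM (3.92), the meiotic cohesin gene Rec8 from 0.0310 ± 0.0273 to 13.6 ± 2.14 FPKM (3.82), and the receptor phosphatase gene Ptprt from 1.99 ± 0.758 to 21.4 ± 3.90 FPKM (2.93). Rtl1 rose from 0.121 ± 0.00777 to 7.14 ± 2.22 FPKM (2.82), but it shares its locus with Mir431, and the library kit is not stated to keep strand, so its reads and those of the transgene cannot be told apart. The largest fall was that of Asgr2, a subunit of the asialoglycoprotein receptor, from 143 ± 59.4 to 0.240 ± 0.305 FPKM (−6.80). Tex13 fell from 16.2 ± 3.37 to 0.315 ± 0.0997 FPKM (−3.69) and AI662270 from 42.2 ± 9.14 to 2.54 ± 0.657 FPKM (−3.60). Gfra3, a receptor for the neurotrophic factor artemin, had a log2 fold change of −3.17, the adenylyl cyclase gene Adcy1 one of −3.08, Ins1 −3.07, the growth factor gene Gdf10 −2.91 and the glutamate receptor family gene Grid1 −2.84. These 16 genes were picked among called genes whose groups do not overlap, so their separation is part of the rule and not a result. Their limma adjusted p ranged up to 0.000148.

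Across the genome, 3454 of 11807 tested genes (29.3%) changed at a limma adjusted p below 0.05. Of these, 1823 rose and 1631 fell, and 469 changed at least 2-fold (244 up, 225 down). The groups did not overlap for 3671 genes (31.1% of those tested, where chance gives 2.86%). The log2 values of the libraries correlated at 0.970 to 0.991 within groups and 0.924 to 0.961 between groups, across genes, which are not independent replicates. The first principal component held 54.9% of the variance and separated the groups, and the second held 16.1%. In the 6 libraries other than 1 and 5, 2870 genes changed, and 2849 of them (99.3%, against 82.2% of all tested genes) had the same sign in the pair of 5 and 1.

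Insulin and granule genes moved in both directions. Of the 21 genes of beta cell identity and insulin, all tested, 2 rose and 4 fell (also 2 and 4 adjusted over the list alone). Ins1 fell from 3332 ± 1405 to 389 ± 126 FPKM (log2 fold change −3.07, limma adjusted p = 0.000148), while Ins2 was at 16593 ± 4937 FPKM in miR-431 and 21988 ± 4820 FPKM in miR-LacZ cells (−0.43, limma adjusted p = 0.344). With quantile normalization Ins2 passed the threshold (−1.14, limma adjusted p = 2.72e-05). That setting gives values by rank, and Mir431 outranked Ins2 in every miR-431 library but was at 0 in the controls. In libraries 5, 6, 7 and 8, Mir431 held 3.47%, 5.47%, 6.04% and 4.57% of summed FPKM, and Ins2 2.87%, 3.15%, 1.69% and 3.67%. The −1.14 is therefore not read as a fall of Ins2. Ins1 and Ins2 are closely related copies, so some reads can be split between them and neither value is exact. In miR-431 cells Ins1 stood at 389 FPKM beside 16593 FPKM of Ins2, so few Ins2 reads can have been placed on Ins1 there. At a like rate in the controls, such splitting would not give 3332 FPKM of Ins1, which argues against it as the source of the fall. Pdx1, a transcription factor of beta cells, fell from 277 ± 49.1 to 192 ± 24.5 FPKM (−0.52), and Ucn3 rose as given above. Of the 19 tested neuroendocrine secretory granule genes, 10 rose and 2 fell (the same adjusted over the list alone). Eno2, a neuronal enolase, rose from 4.97 ± 0.992 to 21.1 ± 5.43 FPKM (1.87), and the granule genes Resp18 from 429 ± 61.7 to 1153 ± 37.7 FPKM (1.43) and Chgb from 608 ± 193 to 1386 ± 440 FPKM (1.18), while Scg2 and Insm1 fell by 0.91 and 0.38. Of 6 tested markers of other islet hormone cells, 3 rose and 0 fell (4 and 1 adjusted over the list alone), with Irx2 at 0.86, Irx1 at 0.66 and Ttr at 0.82. The camera tests did not set these lists apart from other genes (beta cell list adjusted p = 0.544, granule list adjusted p = 0.113, other islet list adjusted p = 0.356), although the granule list passed in some settings given further on (adjusted p = 0.675 with an estimated correlation). The call of Pdx1 ended without miR-LacZ 2 or miR-431 5 (limma adjusted p = 0.0606 and 0.0551), that of Ttr in 5 of the fits that left out 1 library (miR-LacZ 1, 2 or 4, miR-431 6 or 8, adjusted p from 0.0561 to 0.0934), and that of Insm1 in 6 (all but miR-431 5 and 7, adjusted p from 0.0514 to 0.103). With the median of neighbouring genes removed, the log2 fold changes of Insm1, Pdx1 and Ttr were −0.03, −0.31 and 0.78 (limma adjusted p = 0.885, 0.162 and 0.0649), and in the 6 libraries other than 1 and 5 the calls of Insm1 and Ttr ended (limma adjusted p = 0.0612 and 0.0868).

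**Figure D1:**
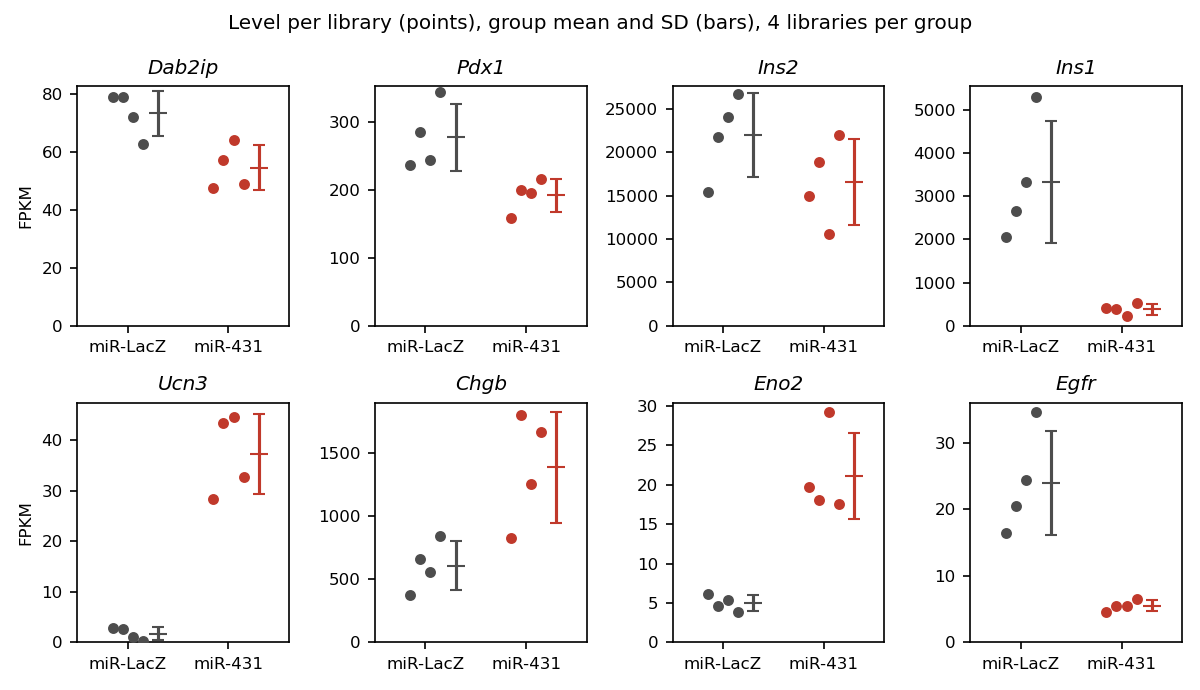
FPKM per library of 8 genes in the miR-LacZ (libraries 1 to 4, grey) and miR-431 (libraries 5 to 8, red) groups, on linear axes from 0, with the points of each group in order of library number. Crossbars mark the group mean and its SD, and the groups do not overlap for Ins1, Ucn3, Eno2, Egfr or Pdx1.

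Of the 14 tested ERK output genes, 2 rose and 1 fell, and 11 did not pass the threshold (2 and 0 adjusted over the list alone). The camera test did not set the list apart from other genes (adjusted p = 0.202, and adjusted p = 0.675 with an estimated correlation). The fry test, which does not compare a list with other genes, passed it upward (fry adjusted p = 0.0185), as it passed 10 of the 25 lists. Dusp4 and Dusp6, phosphatases induced by ERK activity, rose from 3.62 ± 0.411 to 10.1 ± 2.34 FPKM (log2 fold change 1.24, limma adjusted p = 0.000263) and from 0.824 ± 0.307 to 2.60 ± 0.6003 FPKM (0.98, limma adjusted p = 0.00127). Spred1 fell by 0.36. Of 8 tested NF-kB target genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone), namely the chemokine gene Cxcl10, from 2.19 ± 0.456 to 0.592 ± 0.209 FPKM (−1.003). Of 13 p53 target genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 0.69 and Zmat3 by 0.54, and Gdf15 fell by 1.32. Of 20 proliferation genes, 1 rose and 4 fell (0 and 2 adjusted over the list alone), with Aurka at −0.49, Tyms at −0.38 and Ccnb2 at 0.36. Of 15 interferon-stimulated genes, 0 rose and 4 fell (also 0 and 4 adjusted over the list alone), with Oasl2 at −1.20, Oas1a at −1.01 and Oasl1 at −0.75, and the median member at 0.02. Of 16 unfolded protein and integrated stress response genes, 2 rose and 0 fell (0 and 0 adjusted over the list alone), with Ddit3 at 1.12, and of 11 immediate stress genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with Nr4a1 at 1.97. Camera adjusted p was 0.658 for the NF-kB list, 0.544 for the p53, proliferation, interferon and unfolded protein lists and 0.951 for the immediate stress list. Several of these calls ended with 1 library fewer, in 7 of 8 fits for Spred1 (all but that without miR-431 7, adjusted p from 0.0681 to 0.114), in 6 for Ccnb2 (all but miR-LacZ 4 and miR-431 5, 0.0529 to 0.126), in 6 for Zmat3 (all but miR-LacZ 1 and miR-431 7, 0.0510 to 0.102) and in 6 for Ddit3 (all but miR-LacZ 1 and miR-431 8, 0.0577 to 0.0987), and in the 6 libraries other than 1 and 5 for Gdf15, Spred1, Ccnb2 and Ddit3 (0.0783, 0.156, 0.0941 and 0.0711). With the median of neighbouring genes removed, Spred1, Ccnb2, Zmat3 and Ddit3 stood at −0.24, 0.13, 0.35 and 0.96 and did not pass (limma adjusted p = 0.207, 0.414, 0.136 and 0.0687).

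Among genes of cell adhesion and invasion, some rose and others fell. Of 6 tested epithelial genes, 0 rose and 1 fell (1 and 2 adjusted over the list alone), the transcription factor gene Ovol2, from 28.2 ± 15.03 to 3.89 ± 1.20 FPKM (log2 fold change −2.47). Of 7 mesenchymal genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone). Cdh2, which encodes N-cadherin, rose from 47.0 ± 11.2 to 72.9 ± 4.49 FPKM (0.65) and Snai2 from 2.42 ± 0.555 to 4.42 ± 1.07 FPKM (0.66), while Twist1 fell from 4.91 ± 2.16 to 0.170 ± 0.0539 FPKM (−2.27). Of 6 matrix degradation and invasion genes, 1 rose and 2 fell (also 1 and 2 adjusted over the list alone). The membrane-bound metalloprotease gene Mmp15 rose from 3.49 ± 0.204 to 8.77 ± 1.43 FPKM (1.11), and the cathepsin genes Ctsz and Ctsb fell by 0.47 and 0.33. Of 11 integrin and basement membrane genes, 3 rose and 3 fell (the same adjusted over the list alone), with the laminin genes Lamc1 at −0.97, Lamb1 at −0.77 and Lama1 at 0.90. Camera adjusted p was 0.544 for the epithelial, mesenchymal and basement membrane lists and 0.658 for the invasion list, and the mesenchymal list had a median of 0.27 but a mean of −0.03. The calls of Ctsb (all but the fit without miR-LacZ 4, adjusted p from 0.0502 to 0.0737) and Ctsz (all but that without miR-LacZ 1, 0.0513 to 0.0900) ended in 7 of 8 fits that left out 1 library. Both also ended with the median of neighbouring genes removed (−0.20 and −0.26, limma adjusted p = 0.259 and 0.189), and that of Ctsb in the 6 libraries other than 1 and 5 (limma adjusted p = 0.0942).

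Hypoxia, glycolysis and neuronal genes also moved both ways. Of 15 hypoxia and glycolysis genes, 3 rose and 3 fell (the same adjusted over the list alone). Vegfa, an angiogenic growth factor gene, rose from 77.7 ± 9.96 to 134.02 ± 30.8 FPKM (log2 fold change 0.76), the glycolytic gene Pgk1 fell from 471 ± 81.4 to 239 ± 24.7 FPKM (−0.97), and the oxygen sensor gene Egln3 fell by 0.66. Of 17 cholesterol synthesis genes, 3 rose and 0 fell (0 and 0 adjusted over the list alone), with Mvd at 1.01 and Idi1 at 0.87 among them. Of 16 neuronal genes, 5 rose and 2 fell (also 5 and 2 adjusted over the list alone). Gria2, a glutamate receptor gene, rose from 1.84 ± 0.325 to 7.84 ± 1.06 FPKM (1.64), while the neurofilament gene Nefl fell from 40.2 ± 19.1 to 10.8 ± 4.13 FPKM (−1.74). Of 13 microRNA pathway genes, 0 rose and 0 fell with limma (0 and 0 adjusted over the list alone), and of 5 genes of the Dlk1-Dio3 locus, which holds Mir431, 1 rose and 0 fell (also 1 and 0 adjusted over the list alone), namely Rtl1. Camera adjusted p was 0.951 for the hypoxia and microRNA pathway lists, 0.202 for cholesterol synthesis, 0.544 for the neuronal list and 0.303 for the locus. Pgk1, Mvd and Idi1 lie in the chromosome stretches of shifted fold change described further on, and their calls ended when the median of neighbouring genes was removed (−0.22, 0.50 and 0.44, limma adjusted p = 0.348, 0.261 and 0.173). With 1 library fewer, the call ended in 6 fits for Mvd (all but miR-LacZ 1 and 2, 0.0579 to 0.126) and in 4 for Idi1 (miR-LacZ 3 or 4, miR-431 5 or 6, 0.0581 to 0.0888).

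Most markers of other cell types were below the level tested. Of the acinar markers 3 were tested, of which Cela1 fell from 2.14 ± 0.824 to 0.198 ± 0.125 FPKM (log2 fold change −1.36). The only fibroblast marker tested, Pdgfra, fell from 1.84 ± 0.450 to 0.323 ± 0.0295 FPKM (−1.09), while Col1a1 was at 0.250 ± 0.0768 FPKM in miR-431 and 0.424 ± 0.230 FPKM in miR-LacZ cells. Of 2 endothelial markers tested, Plvap rose from 0.586 ± 0.108 to 2.101 ± 0.680 FPKM (0.94), while Pecam1 was at 0.0568 ± 0.0269 FPKM in miR-431 and 0.0969 ± 0.0183 FPKM in miR-LacZ cells. The 1 duct and 2 leukocyte markers tested did not pass the threshold, and the leukocyte gene Ptprc was at 0.0291 ± 0.0203 FPKM in miR-431 and 0.0119 ± 0.0129 FPKM in miR-LacZ cells. Adjusted over the list alone, 0 rose and 1 fell among acinar and among fibroblast markers, 2 rose and 0 fell among endothelial markers, and 0 changed among duct and leukocyte markers. Camera adjusted p was 0.288 for the acinar and endothelial lists, 0.202 for the fibroblast marker, 0.658 for the duct marker and 0.769 for the leukocyte list. None of the 9 mitochondrially encoded genes listed is in the table used here.

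Of the 25 gene lists tested in all, 0 passed an adjusted p of 0.05 with camera at a preset correlation of 0.01, where 4 had an unadjusted p below 0.05. With the correlation estimated per list, 0 passed and 0 had an unadjusted p below 0.05 (smallest adjusted p = 0.675). The fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, passed 10 lists, and its test of change in either direction passed 19. The granule list passed with camera with quantile normalization (adjusted p = 0.0336), with library weights (adjusted p = 0.0363), with the median of neighbouring genes removed (adjusted p = 0.00251), without miR-LacZ 4 (adjusted p = 0.0430) and without miR-431 5 (adjusted p = 0.0442), and the cholesterol list without miR-LacZ 2 (adjusted p = 0.0453).

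**Figure D2:**
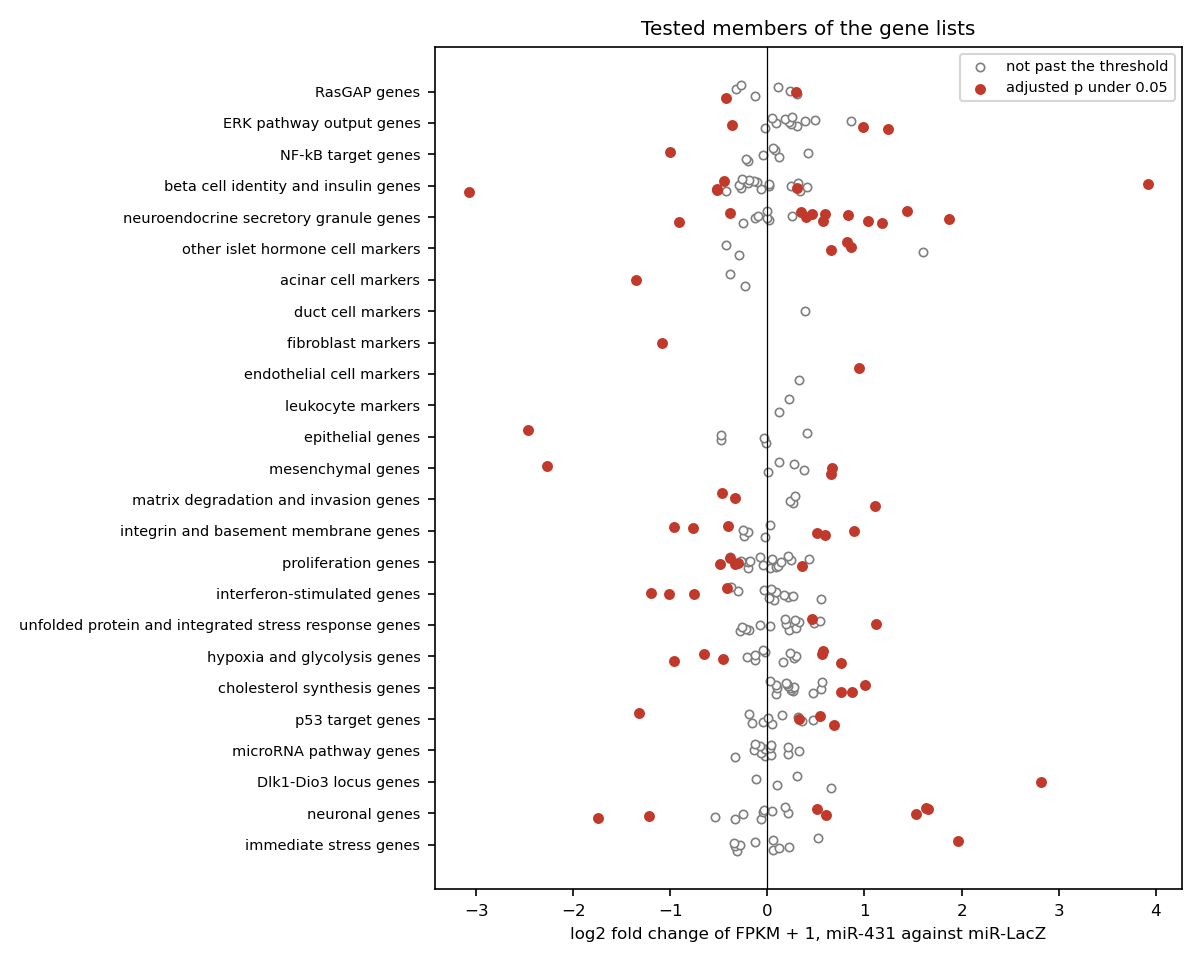
Log2 fold change, miR-431 against miR-LacZ, of each tested member of 25 gene lists (one point per gene). Filled points passed a limma adjusted p of 0.05 and open points did not, and filled points lie on both sides of 0 in 11 of the lists.

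Genes with a sequence match to the microRNA seed did not fall as a group. The match to miR-431-5p (GCAAGAC) was searched in the longest annotated 3′ UTR of 11340 tested genes and found in 924. In a linear model with 3′ UTR length and GC as covariates, its presence had a coefficient of 0.018 (SE 0.016, 95% confidence interval −0.013 to 0.050), and 171 of the 210 arrangements of the same bases had a coefficient at or below it (exact two-sided rank p = 0.381). The coefficients of the other arrangements had an SD of 0.0275, above that SE. The largest in size, such as CGACGAA (0.135) and AACGCGA (−0.127), hold CG, which GCAAGAC does not. Numbers of genes per arrangement are not given here. Whether the interval is too narrow therefore cannot be told from this SD, and the rank p sets the site among partly unlike sites. The match to miR-431-3p (ACGACCT), found in 232 genes, had a coefficient of 0.023 (exact two-sided rank p = 0.338). Of 336 genes with the strongest match class (8mer), 67 rose (19.9%) and 37 fell (11.01%), and of 9307 genes with no match 15.1% rose and 14.4% fell. Among the 8mer genes, the falls were largest for Egfr, the EGF receptor gene (24.0 ± 7.75 to 5.51 ± 0.834 FPKM, log2 fold change −1.90), the fatty acid elongase gene Elovl2 (−1.73), Tmsb15l (−1.40), Limch1 (−1.10), Clrn3 (−1.09) and Hpca (−1.03). In Dab2ip, the longest annotated 3′ UTR (5978 bases) held 0 7mer-m8 matches, 2 7mer-A1 matches and 4 6mer matches, and none of the 7 annotated 3′ UTRs of the gene held a 7mer-m8 match.

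**Figure D3:**
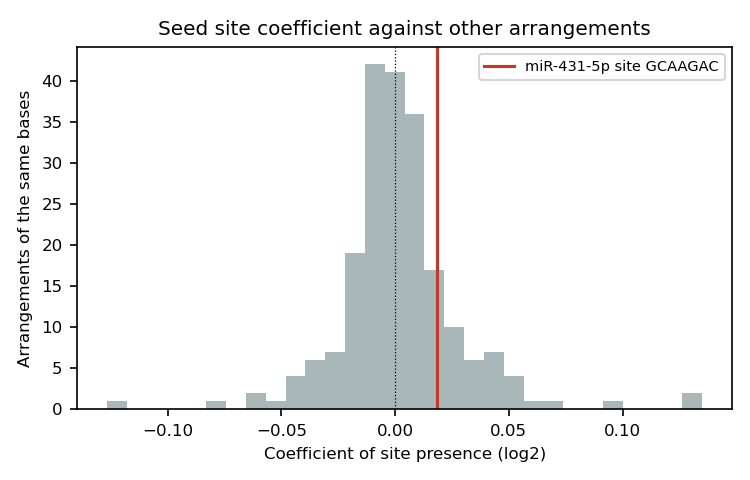
Histogram of the coefficient of site presence, on the log2 scale, for the other arrangements of the bases of the miR-431-5p site, with the site itself as a red line and 0 as a dotted line. The site, at 0.018, lies inside the range of the other arrangements.

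Fold changes were not spread evenly along the chromosomes. In 12 stretches of at least 20 genes, the running median of 31 genes lay beyond 0.3 in size on the log2 scale. These 581 genes included 385 (66.3%) that changed, against 27.4% of the genes elsewhere. Smaller shifts covered whole chromosomes, so the genes elsewhere were not free of them. Of 20 chromosomes, 16 had library medians that differed between the groups (exact permutation test, adjusted p below 0.05). In miR-431, 7 of these were higher and 9 lower. Chromosome 9 had a median of 0.21, and 204 of its genes rose and 28 fell. Chromosome 11 had a median of −0.16, and 70 of its genes rose and 227 fell. The end of chromosome 8 (112.1 to 131.3 Mb, mm9) had a median of 0.54 over 140 genes, of which 102 rose and 3 fell, and its start (3.2 to 10.6 Mb) a median of −0.56 over 29 genes. On chromosome X, 92.0 to 130.2 Mb had a median of −0.79 over 70 genes, of which 3 rose and 55 fell, and on chromosome 13, 3.5 to 19.7 Mb and 23.8 to 48.4 Mb had medians of 0.38 and 0.39. The stretches were picked by their fold changes, so no p-value is given for them. When stretches were picked in the 6 libraries other than 1 and 5 alone, 15 were found, and all 15 had a median of the same sign in the pair of 5 and 1, at 0.15 to 0.63 in size.

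**Figure D4:**
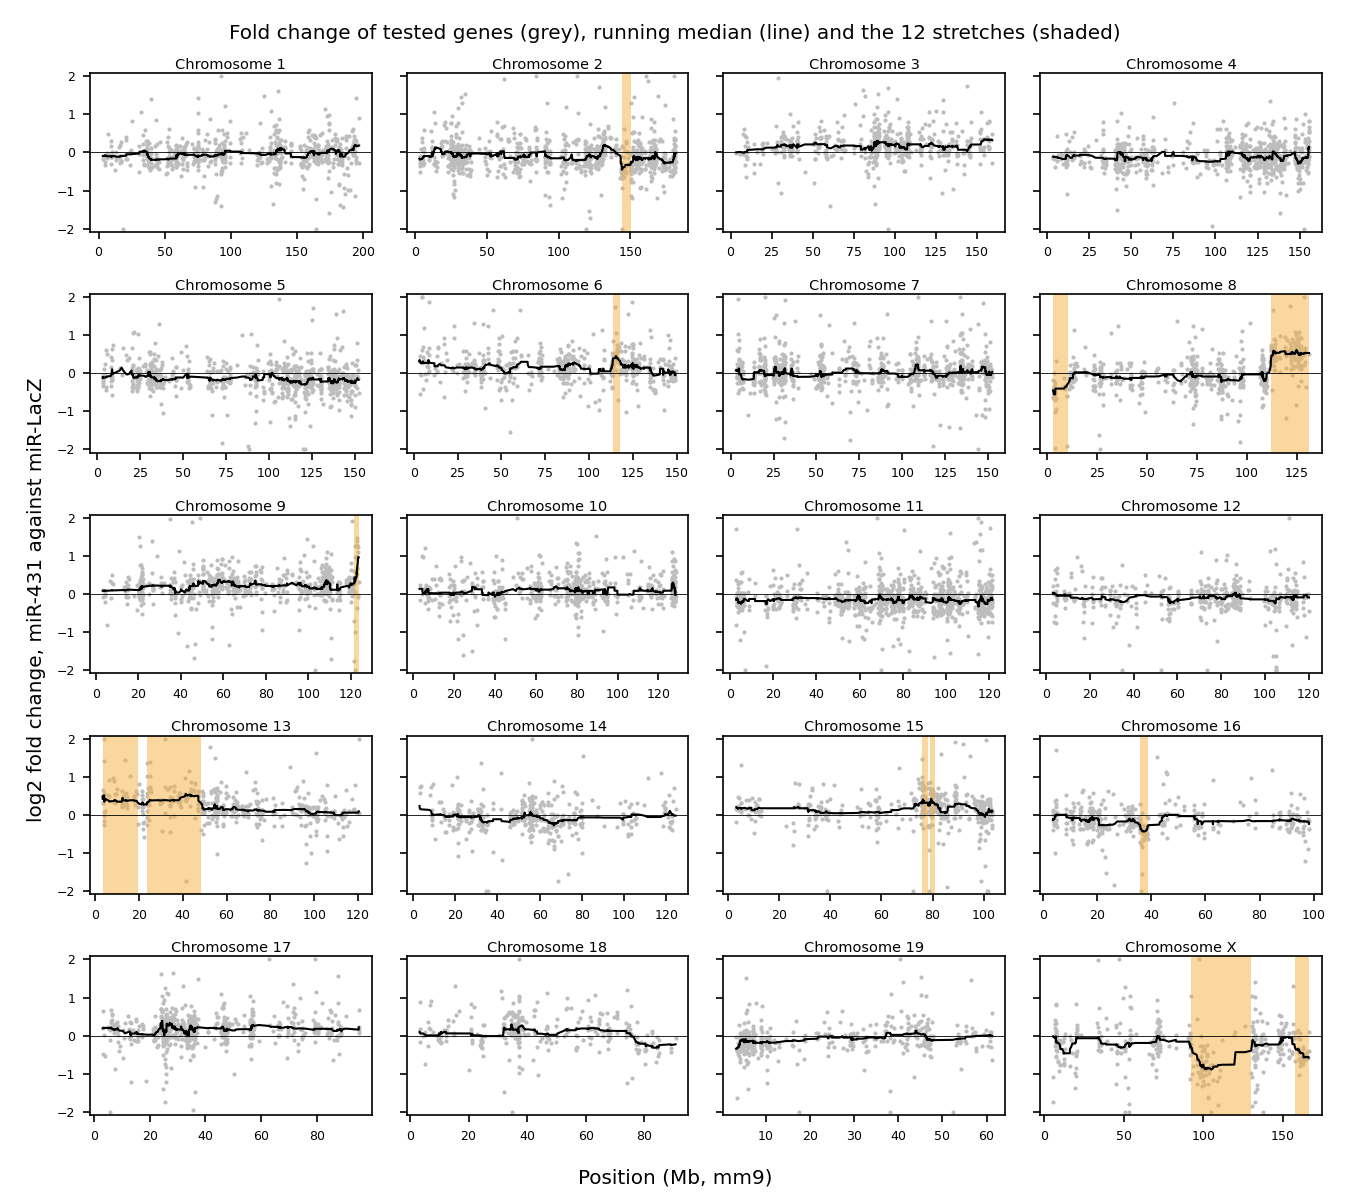
Log2 fold change, miR-431 against miR-LacZ, of tested genes by position in Mb (mm9) on each chromosome, with values beyond 2 in size drawn at the edge. The line is the running median of 31 genes and shading marks the 12 stretches, such as the end of chromosome 8 (median 0.54) and 92.0 to 130.2 Mb of chromosome X (median −0.79).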

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

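The check for outlying libraries was planned, and the tests that weigh the 3 patterns in the other parts were chosen after the results were seen, except that on untested low genes. Among the named genes and Mir431, 131 groups of 4 values were checked, and 5 had a library whose gap to the nearest of the others exceeded Dixon's 95% critical value as a share of the range, where chance alone flags about 6.55. Ptprt was at 27.2 FPKM in miR-431 5 and at 19.1 to 19.9 FPKM in the other miR-431 libraries. Sgce was at 0.0352 FPKM in miR-LacZ 3 and at 0.0160 to 0.0192 FPKM in the other controls. Asgr2 was at 0.694 FPKM in miR-431 8 and at 0.0414 to 0.125 FPKM in the other 3, all far below the controls. Oasl2 was at 9.19 FPKM in miR-LacZ 4 and at 2.46 to 3.57 FPKM in the other controls. Gria2 was at 6.25 FPKM in miR-431 7 against 8.26 to 8.43 FPKM in the other miR-431 libraries.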

How the results depend on the processing

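The settings for 6 libraries, the step pattern, GC and length, and neighbouring genes were chosen after the data were seen, the others before. None of the 1264 values of 64 other genes selected by the rule changed direction, but 94 lost the call, in 12 genes (Ccnb2, Ctsb, Ctsz, Ddit3, Gdf15, Idi1, Mvd, Pdx1, Pgk1, Spred1, Ttr and Zmat3), 11 of which (all but Gdf15) lost it with the local median removed, 8 with no level filter (Ccnb2, Ctsz, Ddit3, Idi1, Mvd, Spred1, Ttr and Zmat3), 7 in the 6 libraries (Ccnb2, Ctsb, Ddit3, Gdf15, Mvd, Spred1 and Ttr) and at most 3 in any other setting of all 8. The count of changed genes (3454, with 1823 up and 1631 down) was 5845 (2858 and 2987) with estimated library weights, 469 (244 and 225) with a 2-fold minimum and 1693 (958 and 735) at an adjusted p of 0.01, and 2480 to 3350 without 1 library (1359 to 1765 up, 1121 to 1585 down). It was 2870 in the 6 libraries other than 1 and 5, 4298 with a term for these 2, 4044 with the GC and length trend removed and 2419 with the local median removed, of which 2669, 3432, 3222 and 1952 were also called in the main comparison. The number of gene lists past the threshold (0) was 1 with quantile normalization, 1 with library weights and 1 with the local median removed, each time the granule list (camera adjusted p = 0.0336, 0.0363 and 0.00251), 10 with fry and 0 to 1 without 1 library. With an estimated correlation no list passed, and the granule list had an adjusted p = 0.675. Dab2ip kept its direction throughout, with log2 fold changes of −0.51 to −0.36 without 1 library (limma adjusted p from 0.0133 to 0.0686, 4 of 8 calls lost), −0.33 in the 6 libraries (adjusted p = 0.108) and −0.34 with the local median removed (adjusted p = 0.0693). Its adjusted p ranged from 0.000659 to 0.0693 in the fits of all 8 libraries (0.0250 with the step term). The cause was not tested, beyond the fewer libraries in some fits. Ins2 passed with quantile normalization only (−1.14, limma adjusted p = 2.72e-05), a setting in which Mir431 outranks it in the miR-431 libraries alone. The seed coefficient did not pass in any setting (0.016 to 0.022 without 1 library). The settings for read counts were not run because the table holds FPKM. No paired analysis was run, because the groups share no replicate number and the labels name no other pairing. Deviations from the group mean correlated across genes at −0.435 to 0.523 between libraries of the 2 groups, most for 1 with 5 (0.523) and 3 with 7 (0.510). Library 2 correlated above 0 with 6 (0.181) and 8 (0.156), and library 4 with 8 (0.306) and 6 (0.292). All other pairs between the groups were below 0. Each control library thus correlated most with the library in the same place in its group's numbering (1 with 5, 2 with 6, 3 with 7, 4 with 8). Library 6 in turn correlated more with 4 than with 2, so these values do not settle a pairing. The unpaired p-values, that of Dab2ip included, leave out any structure that libraries of the 2 groups share.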

Other observations

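The tests on the 3 patterns were chosen after the results were seen, except that on untested low genes, which was set before its value was seen. Some further genes were picked after their values were seen and stand for no tested group. Rbp4, a retinol carrier, fell from 677 ± 134.3 to 108 ± 30.98 FPKM (log2 fold change −2.65), and the transferrin gene Trf from 17.97 ± 8.75 to 2.88 ± 0.729 FPKM (−2.19). The neighbouring alpha-1 antitrypsin genes Serpina1a, Serpina1b, Serpina1c, Serpina1d and Serpina1e stood at −0.93, −1.93, −2.28, −1.63 and −2.0496, but they are near-identical copies and their reads can be split between them.

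The first pattern is the 3454 genes that changed. Of the 35 splits of the 8 libraries into groups of 4, only 1, the real one, gave as many, and the highest other split gave 2. The other splits mix the 2 groups, which widens the spread within each side, so low counts there carry little weight. With 35 splits the real one ranks first by chance in 1 of 35, so chance is unlikely but cannot be excluded. In the 6 libraries other than 1 and 5, 2870 genes were called, so these calls do not rest on those 2 libraries. Of these genes, 99.3% had the same sign in the pair of 5 and 1, against 82.2% of all tested genes. The processing that set libraries 1 and 5 apart fell on 1 library of each group, so signs in that pair do not test it as a source. Shifts of chromosome stretches are not the whole source, since 1952 of the genes stayed changed with the local median removed, but calls such as that of Pgk1 ended (log2 fold change −0.97 before, SE 0.142, and −0.22 after) because its neighbours had moved by a similar amount. Effects of the microRNA, and differences between the 2 cell populations that do not depend on it, stay open and untested, since each group is 1 construct.

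The second pattern is the stretches of shifted fold change, with 766 genes beyond the limit. Only 1 of the 35 splits, the real one, placed as many genes there (highest other 256). The other splits mix the 2 groups, which shrinks a difference between them, while the limit stays fixed. Their lower counts therefore carry little weight. In 100 shuffled gene orders, at most 9 genes lay beyond the limit. Removing the trend with GC and transcript length moved no stretch median by more than 0.0933. Of the 15 stretches picked in the other 6 libraries alone, 15 had the same sign in the pair of 5 and 1. The stretches picked this way do not rest on libraries 1 and 5. The processing that set these 2 libraries apart fell on 1 library of each group, so signs in that pair do not test it as a source. A candidate explanation is chromosome copy number that differs between the cells of the 2 groups, for which genes too low to be tested were examined. In 11 of the 12 stretches their median had the same sign (72 of 99 low genes, with as few as 2 genes in a stretch). Sizes were near on chromosome 8 (112.1 to 131.3 Mb, 0.45 for low and 0.54 for tested genes) and X (92.0 to 130.2 Mb, −0.82 and −0.79). They differed more on chromosome 13 (23.8 to 48.4 Mb, 0.16 and 0.39) and X (157.6 to 166.4 Mb, −1.28 and −0.46). Low genes were compared by ratios of mean FPKM with no 1 added, so sizes are on unlike scales. Differing copy number remains a hypothesis, since joint regulation of neighbouring genes may give the same values and DNA was not analysed here.

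The third pattern is that genes with a miR-431-5p match did not fall as a group. Only 1 of the 35 splits, the real one, gave a coefficient as large in size (0.0184, highest other 0.0178), but its 95% confidence interval held 0 and the size of a coefficient above 0 does not bear on an absent fall, so nothing is drawn from the splits. With the local median removed it was 0.0136, so shifted stretches did not hide a fall. Less 2 SD of the other arrangements, some of them unlike the site, the main coefficient was −0.0366. The lower end of its 95% confidence interval was −0.013. Both argue against a mean fall of 0.05 missed for lack of precision, while smaller falls, or falls in few genes, stay open. Whether the cells' own miR-431 could already act in the controls cannot be told, since mature microRNA was not measured. In miR-LacZ cells Mirg of the same locus stood at 16.3 FPKM. Rtl1, whose position Mir431 shares, stood at 0.121 FPKM there, and Mir431 was listed at 0.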
